A study of Homo sapiens with 30 samples.

How the data were processed

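H3K27ac and H3K4me1 chromatin immunoprecipitation libraries of GM21 human skin fibroblasts were used at day 0 (empty vector) and at days 10, 18, 22 and 32 of oncogenic H-RAS expression, with 2 replicates per mark and day. Of the 30 samples, 20 had a peak list and the 10 inputs were not analysed here. Groups, days and replicate numbers were taken from the labels. Per the submitters' processing notes, the tools included Trimmomatic, Bowtie2, SAMtools, MACS2, deepTools and MultiQC, without versions, and the build was hg19. The names of the peaks in the day 32 lists carry another day number, and day 32 was kept as the labels give it.

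The authors deposited 1 peak list per library, called separately, so replicates could be compared. The deposited score of a peak was found to be 10 times the −log10 p as a whole number for nearly all peaks (at least 99.978% in each list). The deposited fold is a ratio of the peak to its background at the summit, and the deposited −log10 p and −log10 q are those of the authors' caller. The smallest deposited −log10 p was 3.00 to 3.04 in H3K27ac lists and 3.00 to 3.02 in H3K4me1 lists; the threshold itself is not given in the sources used here. The other deposited columns are positions and summit offsets. Score, fold, p and q are the authors' values for a peak and were used only to describe, rank or filter peaks within a list. Read depth is not given in the sources used here. The spacing of the fold values, the step that 1 more fragment at a summit makes, was 0.184 to 0.323 in H3K27ac lists and 0.151 to 0.255 in H3K4me1 lists, and depends on depth in a way that was not calibrated.

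Chromosomes 1 to 22 and X were used, and 262 to 468 peaks per H3K27ac list and 321 to 460 per H3K4me1 list on other sequences were left out. Coordinates are those of the files, counted from 1. No genome or annotation of hg19 was used here; the gene names table belongs to another assembly. The planned gene lists, promoter shares and motif searches were therefore not run, and regions are named by position.

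A region of a time point is a stretch of merged peaks of both replicates overlapped by a peak of each. Gained regions had no peak in either library of the earlier time point by 1 base, and lost regions are the converse. No p-value was given for these counts, since 2 libraries against 2 allow 3 splits; the counts of the 2 mixed splits stand beside them. Similarity was the Jaccard index of covered bases, tested by exact permutation over 945 pairings of the libraries (one-sided) or 120 orders of the days (two-sided). Bins of 200 bases at least 50% covered were counted where all 8 RAS libraries and neither day 0 library held them, or the converse, against 45 choices of 2 libraries (exact, one-sided). Overlap between days 10 and 32 was set beside 100 simulations of unchanged groups, whose detection rates followed a beta distribution fitted to the day 0 pair, and beside the overlap of independent lists. Intervals are exact binomial (Clopper-Pearson, 95%) and cover counting error only.

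The regions to name were fixed before the data were examined. Gained or lost regions within 12.5 kb were stitched and ranked by gained or lost bases, and the first 10 each way were named for H3K27ac at days 10 and 32. The first 3 each way were named for H3K27ac at days 18 and 22 and for H3K4me1 at days 10 and 32. Alternatives fixed at the same time were a −log10 q of 5 or more, lists cut to the shortest of their mark (80273 peaks for H3K27ac and 111381 for H3K4me1, the strongest by −log10 q), 50% coverage for overlap, merged regions in place of bins, pairings within the replicate block, and leaving out each replicate. Settings without day 18, and the comparison of similarity to day 0 with day (libraries moved singly, or whole days moved over 24 orders), were chosen after seeing the data.

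Interval arithmetic and the region counts were tested on simulated data. Over 162294 merged H3K27ac regions with 200 seeded gains and 200 seeded losses between day 0 and day 10, 76.5% of gains and 79.5% of losses were recovered, and 2.09% and 2.04% of unchanged regions were called. Over 244697 H3K4me1 regions the recovered shares were 80.0% and 71.5%, and the called shares of unchanged regions 2.17% and 2.11%. Seeded regions had set detection rates, so the recovered shares follow from those rates and do not measure sensitivity in the deposited lists. Unchanged H3K27ac regions called gained and lost numbered 3379 and 3299, beside 9245 and 5265 observed at day 32. For H3K4me1 they numbered 5309 and 5153, beside 12757 and 9258. Unchanged regions took their detection rate over all 10 libraries of the mark, so regions that truly differ between days entered with intermediate rates. The simulated counts also compare day 10 with day 0 over regions merged across all days. They are therefore no estimate of the false calls among the regions observed at day 32. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.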

Results

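H3K27ac and H3K4me1 were profiled by chromatin immunoprecipitation and sequencing in GM21 human skin fibroblasts that carried an oncogenic form of H-RAS, which drives fibroblasts into senescence, a lasting arrest of proliferation. H3K27ac marks active promoters and enhancers, and H3K4me1 marks enhancers whether or not they are active. Cells with an empty vector served as day 0, and RAS cells were taken at days 10, 18, 22 and 32, a course that the series describes as entry into senescence and exit from it. No empty vector library was available at a later day. Differences from day 0 therefore cannot be assigned to RAS rather than to time in culture or to the preparation of a day. Each mark had 2 libraries at each of 5 time points, which gives 20 peak lists, and 10 input libraries were not analysed here. The labels say that the chromatin of a time point was pooled from several biological replicates, so the replicates may be technical. Every p-value below measures only the spread between these libraries or days, or between chromosomes where those were permuted.

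The H3K27ac lists held 80535 to 132334 peaks and covered 53.6 to 94.6 Mb. The H3K4me1 lists held 111741 to 216729 peaks and covered 53.3 to 160 Mb. H3K27ac covered 66.2 ± 14.5 Mb at day 0, 57.9 ± 6.09 Mb at day 10, 88.4 ± 8.73 Mb at day 18, 65.0 ± 0.124 Mb at day 22 and 73.5 ± 3.13 Mb at day 32 (SD, n = 2 each). H3K4me1 covered 129 ± 2.29 Mb at day 0, 97.3 ± 7.29 Mb at day 10, 107 ± 75.3 Mb at day 18, 108 ± 7.39 Mb at day 22 and 137 ± 8.21 Mb at day 32 (SD, n = 2 each). The H3K4me1 libraries of day 18 differed most, with 216729 peaks in replicate 1 and 111741 in replicate 2. In H3K27ac, 18.1% of the peaks of day 18 replicate 1 were in no other H3K27ac list, against 1.60% to 8.29% in the other 9 lists. Read depth is not given in the sources used here, so how far a list's length follows depth is unknown.

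The first question was whether time points differed by more than their replicates. On average, peak lists of the same day shared more bases than lists of different days for both marks, though not at day 18. For H3K27ac the mean Jaccard index, the shared bases divided by the bases in either list, was 0.639 over the 5 same-day pairs and 0.500 over the other pairs. For H3K4me1 it was 0.551 and 0.480. Among all ways to sort the 10 libraries into 5 pairs, the one-sided exact permutation p was 0.00106 for H3K27ac, the smallest these pairings can give, and 0.00529 for H3K4me1, where more than 1 other pairing reached 0.559 or more (Benjamini-Hochberg over the 2 marks 0.00212 and 0.00529). The 2 day 18 lists were the least alike of the same-day pairs, with an index of 0.498 for H3K27ac and 0.315 for H3K4me1. The first was below the mean of the pairs of different days. The second was below every H3K4me1 pair of different days, the lowest of which had 0.317. No relation of similarity to the distance in days was detected: Spearman's rho over the 10 pairs of days was 0.378 for H3K27ac and 0.348 for H3K4me1, with two-sided exact permutation p of 0.350 and 0.400 over 120 orders of the days (both 0.400 after adjustment).

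**Figure D1:**
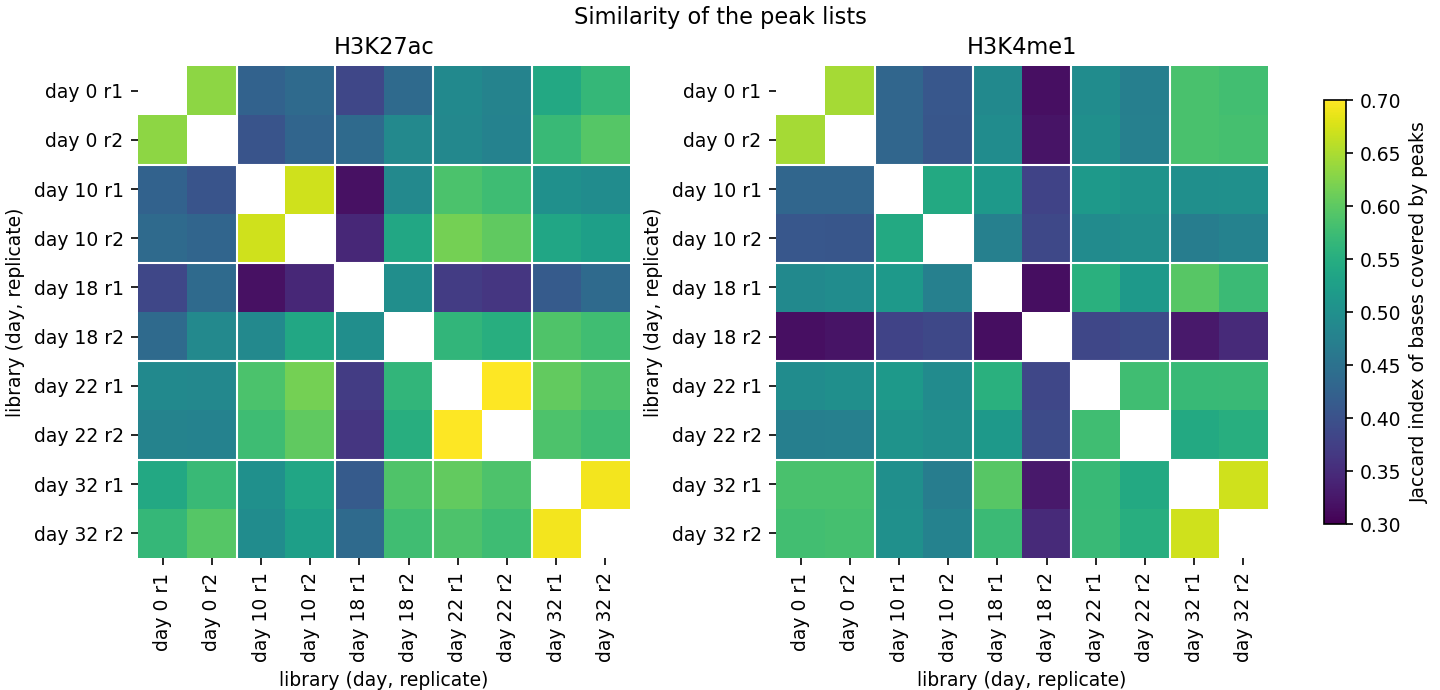
Jaccard index of bases covered by peaks for each pair of the 10 libraries of a mark, ordered by day and replicate (r1, r2); the colour scale has no unit and white marks a library with itself. Same-day pairs of H3K27ac reach 0.633 to 0.699 except at day 18, where the pair has 0.498.

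At day 10 the H3K27ac landscape differed from day 0 in both directions. A region here is a stretch of merged peaks held by both replicates; 12932 regions of day 10 had no peak in either day 0 library (gained, 21.0% of 61452), and 15410 regions of day 0 had none in either day 10 library (lost, 25.0% of 61536). The cluster with most gained bases lay on chromosome 6 at 130741318 to 130824450 (hg19), where 15 gained regions held 15811 bases and H3K27ac peaks covered 22.1 ± 2.24 kb at day 10 against 1.90 ± 0.456 kb at day 0 (SD, n = 2). On chromosome 1 at 152714587 to 152756286, where neither day 0 library had a peak, H3K27ac covered 12.2 ± 1.16 kb at day 10. The cluster with most lost bases lay on chromosome 17 at 75425488 to 75476388, where coverage was 17.1 ± 5.77 kb at day 0 and 1.47 ± 0.298 kb at day 10. No annotation of the files' build was used, so regions are named by position.

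Other H3K27ac clusters gained at day 10 lay on chromosome 13 at 66484749 to 66507807, chromosome 3 at 158901520 to 158930997, chromosome X at 9098049 to 9139974, chromosome 6 at 64484673 to 64506050, chromosome 8 at 23640432 to 23653406, chromosome 12 at 25944731 to 25965936, chromosome 1 at 222234386 to 222262986 and chromosome 4 at 75387520 to 75412569. The 10 named gained clusters spanned 13.0 to 83.1 kb and held 4 to 15 gained regions each. Lost clusters included chromosome 2 at 36594331 to 36658414, with 18 lost regions, chromosome 1 at 115822861 to 115860961, with 16, and chromosome 16 at 70709986 to 70746035, with 8. The others lay on chromosome 17 at 75375852 to 75408981, chromosome 1 at 22222939 to 22254916, chromosome 5 at 148791336 to 148830645, chromosome 22 at 45866802 to 45934303, chromosome 13 at 110957686 to 110994196 and chromosome 2 at 239773254 to 239796305. With 2 libraries against 2 there are 3 splits, so an exact two-sided test cannot go below 0.333 and none was run. The 2 splits that mix the days gave at most 2210 regions either way. Without day 10 replicate 1 the counts were 25587 gained and 17261 lost, and without day 10 replicate 2 they were 21535 and 20248, so the larger side turned. Without day 0 replicate 1 and replicate 2 the lost count was 39180 and 23788. A region needs a peak in both libraries of its own day, so leaving out 1 of them tends to raise that day's side. The turns of the larger side here and below went that way, and by themselves they do not show that the balance rests on 1 library. Losses were 25160 when only peaks overlapping by 50% counted as shared.

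**Figure D2:**
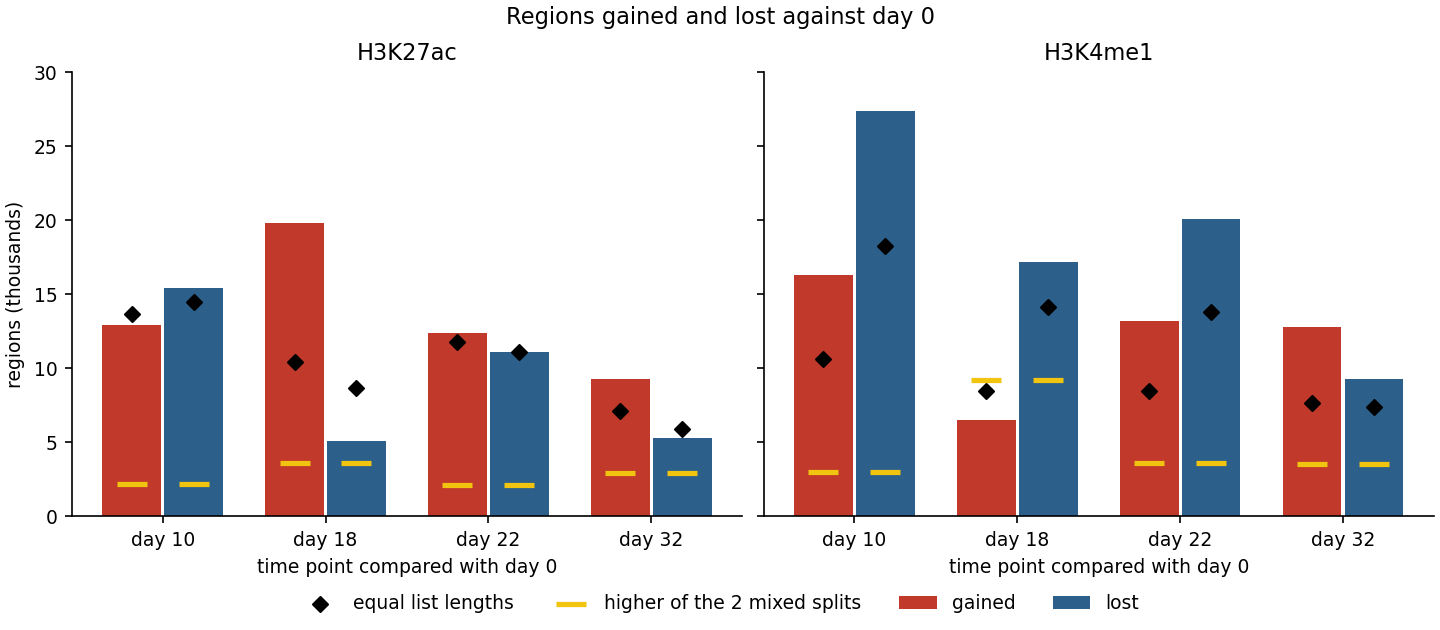
Bars give the number of regions gained and lost at each RAS day against day 0, diamonds the number with lists cut to equal length, and yellow dashes the higher of the 2 splits that mix days. H3K4me1 losses at day 10 (27359) are the tallest bar, and the mixed split (9239) exceeds H3K4me1 gains at day 18 (6503).

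By day 32, 9245 H3K27ac regions were gained and 5265 lost against day 0, against 12932 and 15410 at day 10, a difference that was not tested. The cluster with most gained bases lay on chromosome 6 at 138030589 to 138071798, where H3K27ac covered 12.4 ± 1.10 kb at day 32 and 0.948 ± 0.674 kb at day 0. On chromosome 21 at 39652284 to 39703107 coverage was 36.7 ± 2.81 kb against 13.5 ± 2.07 kb, and on chromosome 18 at 52544658 to 52556820 it was 5.41 ± 0.00283 kb against no peak in either day 0 library. The cluster with most lost bases lay on chromosome 1 at 115825454 to 115864007, where 16 lost regions held 12960 bases and coverage was 2.61 ± 0.238 kb at day 32 against 16.7 ± 6.43 kb at day 0 (SD, n = 2 throughout). This stretch was also among the named lost clusters of days 10, 18 and 22.

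The remaining clusters gained at day 32 lay on chromosome 8 at 23646389 to 23667198, chromosome 14 at 91691223 to 91717585, chromosome 4 at 75231027 to 75242729, chromosome 5 at 159887863 to 159912714, chromosome 2 at 113574742 to 113599782, chromosome 1 at 209819653 to 209850540 and chromosome 11 at 128442979 to 128452958. Lost clusters also lay on chromosome 20 at 48190090 to 48213161, chromosome 2 at 235882971 to 235919947, chromosome 5 at 135364216 to 135380222, chromosome 9 at 137688402 to 137708126 and chromosome 1 at 22222939 to 22240425. Smaller ones lay on chromosome 11 at 61595503 to 61602319, chromosome 7 at 45955592 to 45964399, chromosome 2 at 47230652 to 47236968 and chromosome 2 at 121517497 to 121537594. At the chromosome 11 and chromosome 7 sites no library of day 10 or day 22 had an H3K27ac peak. Mixed splits gave at most 2907 regions. Gains made up 63.7% of the changed regions at day 32, and 54.7% with lists of equal length (7130 gained and 5910 lost), a smaller margin. Without day 0 replicate 1 there were 10335 gained and 21527 lost, which turned the larger side; gains were 17847 without day 0 replicate 2, 19838 without day 32 replicate 1 and 23280 without day 32 replicate 2, and losses 9275 without day 0 replicate 2. At 50% overlap 15769 were gained and 9417 lost.

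At day 18, 19842 H3K27ac regions were gained and 5117 lost against day 0. The leading gained cluster lay on chromosome 2 at 113539441 to 113591831, where 12 regions held 20620 gained bases; H3K27ac covered 6.24 ± 0.568 kb there at day 0, 9.38 ± 0.383 kb at day 10, 27.8 ± 1.18 kb at day 18, 15.0 ± 0.0523 kb at day 22 and 18.7 ± 0.544 kb at day 32 (SD, n = 2). The next, on chromosome 6 at 138012953 to 138072065, held 18544 gained bases and overlapped the leading cluster of day 32, and another lay on chromosome 8 at 23685748 to 23716910. Lost clusters lay on chromosome 1 at 115825454 to 115864007, chromosome 2 at 36613999 to 36648245 and chromosome 8 at 59767735 to 59795122. The preponderance of gains depended on list length: gains were 79.5% of changed regions with all peaks and 54.6% with lists of equal length, where 10404 were gained and 8653 lost. Mixed splits gave up to 3623 regions. Gains were 45507 without day 18 replicate 1 and 54460 without replicate 2, and losses were 18172 and 8862 without day 0 replicates 1 and 2 and 8719 and 11519 without day 18 replicates 1 and 2. At 50% overlap 8923 were lost.

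At day 22, 12393 H3K27ac regions were gained and 11082 lost. The leading gained cluster, on chromosome 4 at 75397809 to 75412916, had 11.1 ± 1.28 kb of H3K27ac at day 22 against 0.253 ± 0.0276 kb at day 0, and overlapped a cluster gained at day 10. The others lay on chromosome 5 at 152922936 to 152949089 and at 124376378 to 124385906. Lost clusters lay on chromosome 1 at 115822861 to 115864007, chromosome 16 at 70709986 to 70746035 and chromosome 2 at 36603250 to 36658414, each overlapping a cluster lost at day 10. Mixed splits gave at most 2086 regions. Without day 0 replicate 1 the counts were 13432 gained and 32100 lost, which turned the larger side; gains were 19212 without day 0 replicate 2, 24509 without day 22 replicate 1 and 21486 without day 22 replicate 2, and losses 17626 without day 0 replicate 2. At 50% overlap there were 18925 gained and 19081 lost, which also turned the larger side.

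**Figure D3:**
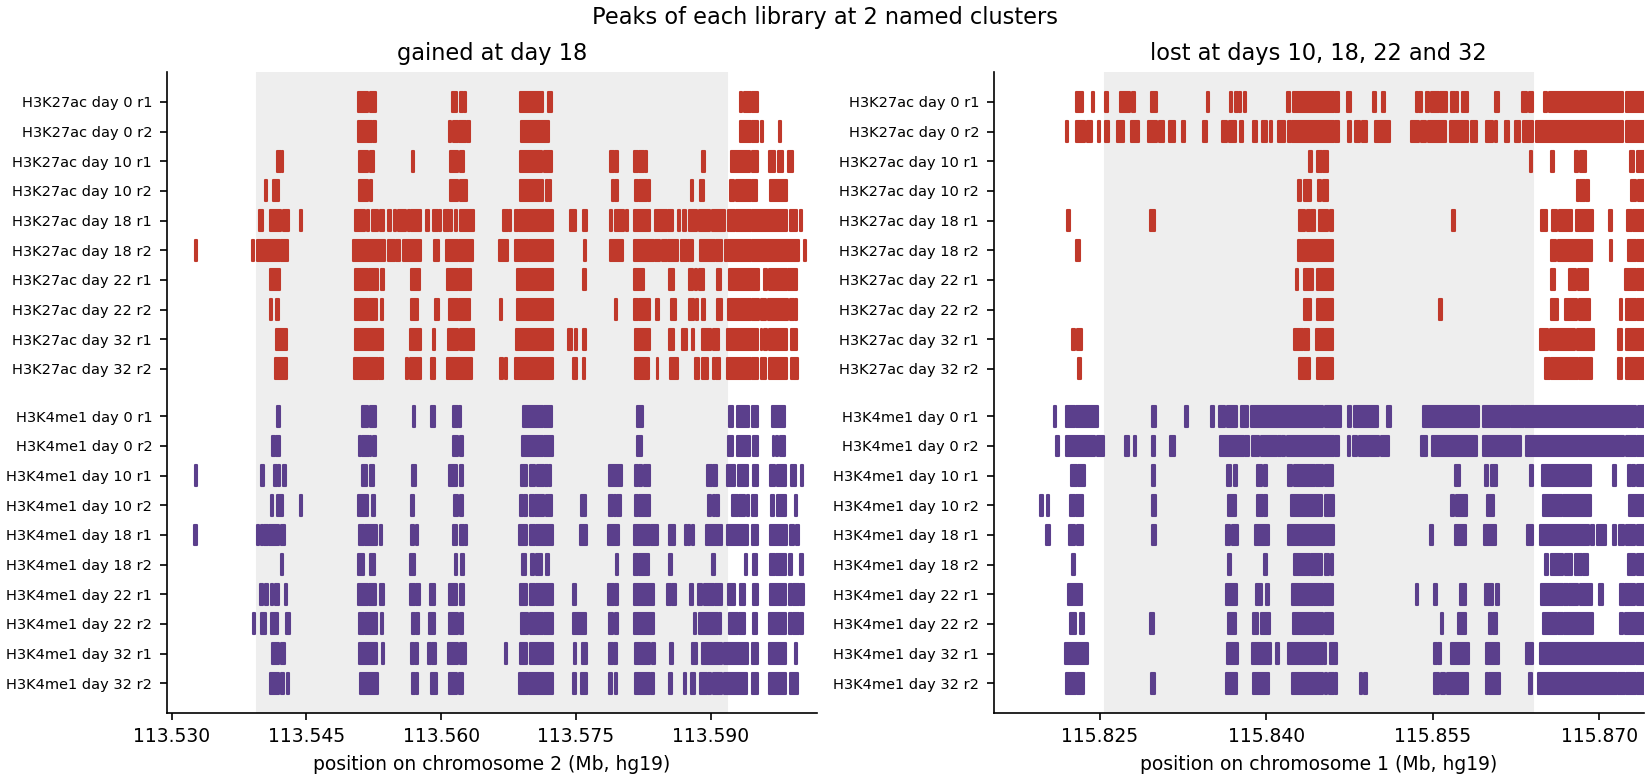
Peaks of each library (bars, H3K27ac red and H3K4me1 purple) along 2 named clusters shaded grey, by position in Mb (hg19): the cluster gained at day 18 on chromosome 2 and the cluster lost at day 32 on chromosome 1. H3K27ac peaks cover 27.8 ± 1.18 kb of the first at day 18 against 6.24 ± 0.568 kb at day 0, and 2.61 ± 0.238 kb of the second at day 32 against 16.7 ± 6.43 kb at day 0 (SD, n = 2).

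Between day 10 and day 32, 14894 H3K27ac regions were gained and 6706 lost, with at most 1677 in a mixed split. Gains made up 69.0% of these, and 57.2% with lists of equal length (10847 gained, 8125 lost). Gains were 28547 and 30416 without day 32 replicates 1 and 2, and losses 16153 and 12658 without day 10 replicates 1 and 2. At 50% overlap 24564 were gained and 10689 lost. For H3K4me1, 22588 regions were gained and 7234 lost over the same interval, with at most 4041 in a mixed split. Gains made up 75.7% of the H3K4me1 changes and 86.3% when peaks needed a −log10 q of 5 or more (20762 gained, 3289 lost), or 71.7% with lists of equal length (13328 gained, 5255 lost). H3K4me1 gains were 36563 without day 10 replicate 1, 45317 without day 32 replicate 1 and 50353 without day 32 replicate 2; losses were 20330 and 24117 without day 10 replicates 1 and 2, and 12373 without day 32 replicate 1. At 50% overlap 46504 were gained and 13547 lost.

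H3K4me1 lost more regions than it gained at day 10, with 27359 regions of day 0 lost and 16305 regions of day 10 gained. The leading lost cluster lay on chromosome 9 at 137549470 to 137607683, where H3K4me1 covered 34.0 ± 2.15 kb at day 0, 10.1 ± 0.273 kb at day 10 and 19.2 ± 1.54 kb at day 32 (SD, n = 2). Others lay on chromosome 7 at 134371892 to 134417346 and chromosome 9 at 125798907 to 125832737. The leading gained cluster lay on chromosome 6 at 64484869 to 64519236, with 10.8 ± 0.579 kb at day 10 against 3.08 ± 0.158 kb at day 0, and overlapped a cluster that gained H3K27ac at day 10. The next, on chromosome 7 at 111791118 to 111843575, had 12.52 ± 0.952 kb at day 10, 1.49 ± 0.387 kb at day 0 and 11.8 ± 1.56 kb at day 32, and the last lay on chromosome 6 at 138013448 to 138060467. Mixed splits gave at most 2988 regions, and gains were 37.3% of the changed regions, or 25.99% at a −log10 q of 5 or more (8337 gained, 23738 lost). Without day 10 replicate 2 the counts were 39320 gained and 34397 lost, which turned the larger side; gains were 35288 without day 10 replicate 1 and losses 55929 and 54044 without day 0 replicates 1 and 2. Gains were 10648 with lists of equal length, and at 50% overlap 27541 were gained and 51588 lost.

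By day 32, 12757 H3K4me1 regions were gained and 9258 lost against day 0. On chromosome 11 at 93716784 to 93768019, H3K4me1 covered 12.1 ± 0.503 kb at day 32 against 0.509 ± 0.298 kb at day 0 (SD, n = 2). Gained clusters also lay on chromosome 18 at 52544084 to 52574680, overlapping a cluster that gained H3K27ac at day 32, and on chromosome 7 at 111783027 to 111826002. On chromosome 1 at 845786 to 880314, H3K4me1 covered 8.23 ± 0.114 kb at day 0, 0.817 ± 0.617 kb at day 10 and 0.967 ± 0.194 kb at day 32; the other lost clusters lay on chromosome 9 at 137566692 to 137603433 and chromosome 2 at 129122315 to 129154448. Mixed splits gave at most 3533 regions. Without day 0 replicate 1 the counts were 19373 gained and 26148 lost, and without day 0 replicate 2 they were 21399 and 24706, so the larger side turned; gains were 29376 and 33635 without day 32 replicates 1 and 2, and losses 16526 without day 32 replicate 1. Gains were 57.9% of the changed regions, or 50.9% with lists of equal length (7626 gained, 7361 lost), and at 50% overlap 26156 were gained and 18525 lost.

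At day 22, 13177 H3K4me1 regions were gained and 20075 lost, with at most 3578 in a mixed split. Gains at day 22 were 30965 and 35404 without day 22 replicates 1 and 2, and losses 44769 and 43307 without day 0 replicates 1 and 2 and 31975 without day 22 replicate 1; leaving out day 22 replicate 2 turned the larger side, with 26556 lost. Gains at day 22 were 8463 with lists of equal length and 8002 at a −log10 q of 5 or more, and at 50% overlap 23808 were gained and 39037 lost. At day 18, 6503 H3K4me1 regions were gained and 17197 lost, but a split that mixed the days gave 9239, so the gains did not exceed what the spread between the day 18 libraries produced. Gains at day 18 were 27.4% of the changed regions, or 37.5% with lists of equal length (8495 gained, 14154 lost). They were 9970 without day 0 replicate 2, 11086 without day 18 replicate 1 and 63226 without day 18 replicate 2, and the last setting had 17611 lost, which turned the larger side; losses were 38712 and 37390 without day 0 replicates 1 and 2 and 60686 without day 18 replicate 1. Gains at day 18 were 3476 at a −log10 q of 5 or more, and at 50% overlap 15014 were gained and 29953 lost.

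Some stretches carried a mark in all 8 RAS libraries and neither day 0 library, or the converse. H3K27ac marked 6902 bins of 200 bases (1.38 Mb) in the first way and 8727 (1.75 Mb) in the second; H3K4me1 marked 5927 (1.19 Mb) and 26627 (5.33 Mb). Against the 45 ways to choose 2 of 10 libraries, the one-sided exact permutation p was 0.0444 and 0.0667 for H3K27ac gains and losses and 0.133 and 0.0222 for H3K4me1 gains and losses. Most of these choices mix days, and libraries of a day were more alike on average, so a pair from 1 day is favoured whatever its treatment. These p-values, and those of the settings below, therefore do not show that day 0 stood apart more than another day would. After Benjamini-Hochberg adjustment over the 4 tests these were 0.0889, 0.0889, 0.133 and 0.0889. The smallest exact permutation p that 45 choices can give is 0.0222, reached by H3K4me1 losses, and a test that alone reaches it cannot pass 0.05 after adjustment over 4. Day 10 rather than day 0 gave the largest H3K27ac count of bins found in all 8 other libraries, 8752, and day 18 the largest count of bins found in no other library, 28705. With days kept whole, day 0 gave the largest count only for H3K4me1 losses, 26627 against at most 7724 for another day. No test was run with whole days. Among pairs of libraries with more H3K4me1 bins held by all 8 others than day 0 were the day 10 pair, with 6636, and day 10 replicate 2 with day 18 replicate 2, with 16983. With merged regions in place of bins, 2 of the 4 adjusted values passed 0.05: H3K27ac gains (1882 regions) and H3K4me1 losses (5117 regions), each with an adjusted exact permutation p of 0.0444. H3K4me1 gains were 3722 bins at a −log10 q of 5 or more (exact permutation p = 0.178). Without the day 18 libraries, a setting chosen after seeing the data, the counts were 14596 and 18910 for H3K27ac and 12453 and 32543 for H3K4me1, with adjusted exact permutation p of 0.0476, 0.0476, 0.0714 and 0.0476 over 28 pairs.

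Similarity to day 0 was then compared across the RAS days, a comparison chosen after seeing the data. H3K27ac lists of day 10 had a mean Jaccard index of 0.425 with those of day 0 (4 library pairs, 0.403 to 0.439), day 18 of 0.437, day 22 of 0.483 and day 32 of 0.569 (0.541 to 0.595). For H3K4me1 the means were 0.420, 0.406, 0.485 and 0.583. The day 0 replicates had indices of 0.633 and 0.647 with each other, above every value at day 32. Over the 8 RAS libraries, similarity to day 0 against day gave Pearson's r of 0.923 and Spearman's rho of 0.878 for H3K27ac, and r of 0.766 and rho of 0.830 for H3K4me1. The 2 libraries of a day are not independent, and with whole days moved over the 24 orders of the 4 RAS days the two-sided exact permutation p was 0.0417 for r, the smallest these orders can give, and 0.167 for rho for H3K27ac (adjusted over the 2 marks 0.0833 and 0.167). For H3K4me1 it was 0.125 for r and 0.0833 for rho (exact permutation, adjusted 0.125 and 0.167), so neither mark passed 0.05 after adjustment. Moving single libraries, which treats them as independent, gave exact permutation p of 0.00317 and 0.0103 for r and rho of H3K27ac (adjusted 0.00635 and 0.0198) and 0.0246 and 0.0198 for H3K4me1 (adjusted 0.0246 and 0.0198). Without the day 32 libraries, the 2 farthest from the median day, r was 0.733 and rho 0.717 for H3K27ac (exact permutation p = 0.111 and 0.178 over 6 libraries). For H3K4me1 r was 0.354 and rho 0.598 (exact permutation p = 0.511 and 0.267). Moving single libraries thus gave p under 0.05 for neither mark without day 32, while r and rho stayed positive and r fell most for H3K4me1. Without day 18, r was 0.974 and 0.975 and rho 0.956 for both marks.

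**Figure D4:**
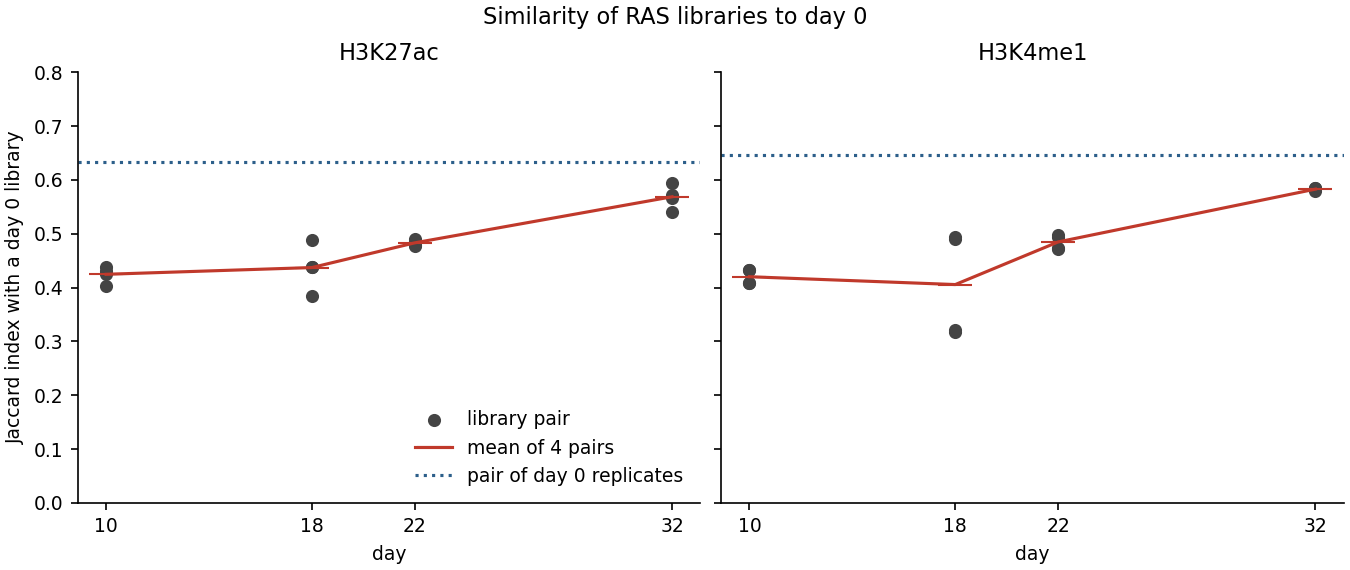
Jaccard index (no unit) of each RAS library with each day 0 library against day; points are library pairs, the red line joins the means of 4 pairs and the dotted line is the pair of day 0 replicates. The H3K27ac mean is 0.425 at day 10 and 0.569 at day 32, and the H3K4me1 mean 0.420 and 0.583.

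The series title names scars on chromatin, so regions changed at day 10 were followed to day 32. Of the 12932 H3K27ac regions gained at day 10, 31.9% had a peak in both day 32 libraries (exact binomial 95% interval 31.0% to 32.7%, counting error only) and 45.01% in neither. Of the 15410 lost, 49.4% had a peak in both day 32 libraries again and 30.2% in neither. For H3K4me1, 37.6% of the 16305 gained regions had a peak in both day 32 libraries and 36.5% in neither, and 47.3% of the 27359 lost regions had one in both and 27.6% in neither. Per day 32 library, 43.4 ± 5.19% of the gained H3K27ac regions and 50.5 ± 3.86% of the gained H3K4me1 regions held a peak (SD, n = 2). Without day 0 replicate 1 the share of lost H3K27ac regions with a peak in both day 32 libraries was 30.7%.

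Each of the 10 named H3K27ac clusters gained at day 10 had more coverage in both day 32 libraries than in both day 0 libraries and less than in both day 10 libraries. On chromosome 6 at 130741318 to 130824450, H3K27ac covered 9.68 ± 2.35 kb at day 32, and on chromosome 1 at 152714587 to 152756286 it covered 2.22 ± 1.07 kb (SD, n = 2). Of the 10 clusters lost at day 10, 7 lay between day 0 and day 10 in the same sense. The cluster on chromosome 17 at 75425488 to 75476388 was not among those 7, with 13.1 ± 0.980 kb at day 32 against 17.1 ± 5.77 kb at day 0. Of the 3 named H3K4me1 clusters gained at day 10, 3 had more coverage in both day 32 libraries than in both day 0 libraries and 0 had less than in both day 10 libraries, while the 3 lost ones lay between day 0 and day 10. These clusters were picked for their difference between day 10 and day 0, which by itself favours a later value in between. Of the 9245 H3K27ac regions gained at day 32, 47.9% were held by both day 10 libraries and 5.59% by no earlier RAS library. Of the 5265 lost at day 32, 88.3% had no peak at day 10.

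Gains at days 10 and 32 share their day 0 controls. Over merged regions, 30.4% of those gaining H3K27ac at day 10 also gained it at day 32, against 8.59% for independent lists and 28.4% in simulations of unchanged groups that shared the controls (100 draws). For losses the shares were 32.5%, 9.20% and 30.6%. For H3K4me1 gains they were 34.9%, 12.3% and 29.9%, and for losses 30.4%, 7.91% and 28.8%. The simulations changed fewer regions, on average 2493 H3K27ac gains at day 10 against 10606 observed. These shares are bounded by the shorter day 32 lists, at 36.2% for H3K27ac losses and 36.6% for H3K4me1 losses. From the other side, 46.0% of the regions gaining H3K27ac at day 32 had gained it at day 10, against 13.01% for independent lists and 28.4% in the simulations, and 89.8% of those losing it, against 25.4% and 30.5%. For H3K4me1 gains the shares were 40.3%, 14.3% and 29.9%, and for losses 83.1%, 21.6% and 28.9%. Splitting the controls would leave 1 library each, so part of the excess over independent lists may come from the shared controls.

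**Figure D5:**
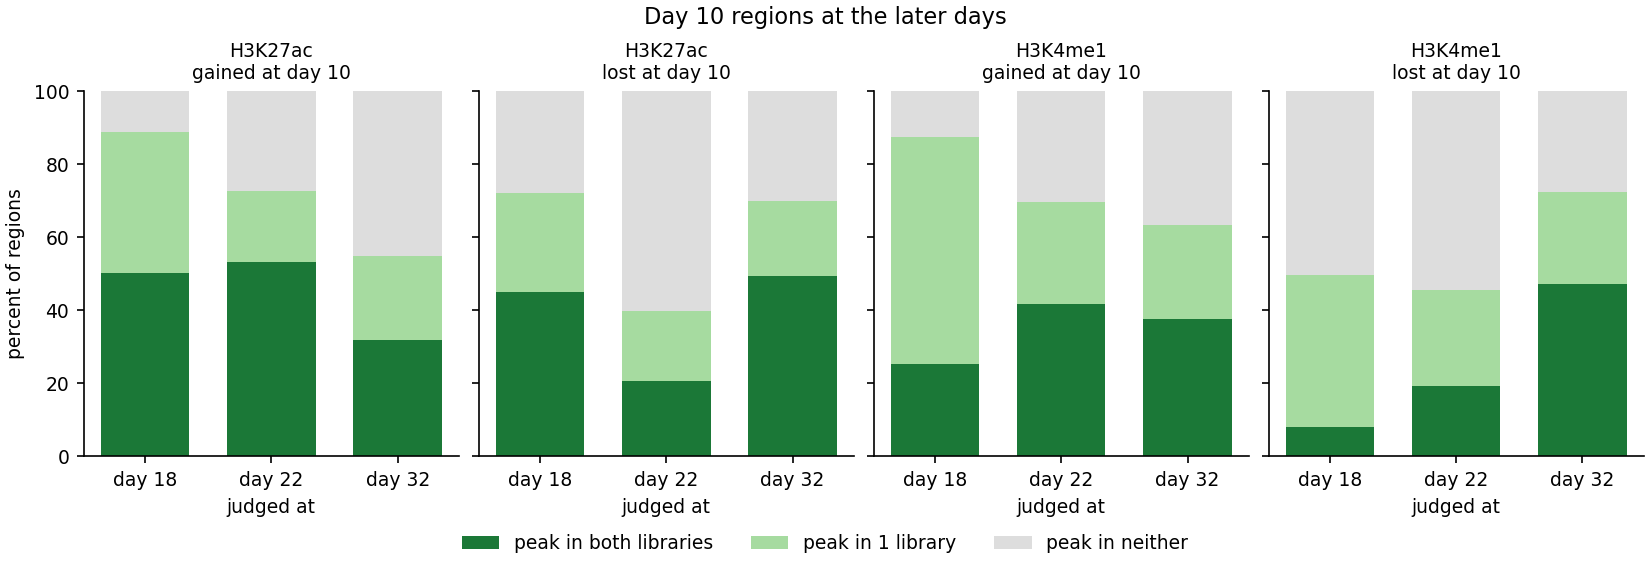
Percent of regions gained or lost at day 10 that had a peak in both libraries, in 1 or in neither at days 18, 22 and 32, for each mark. Gained H3K27ac regions with a peak in both libraries go from 53.1% at day 22 to 31.9% at day 32.

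The marks were then compared at the same places. H3K27ac regions gained at day 10 lay on an H3K4me1 region of day 0 in 50.5% of cases and on one of day 10 in 73.8%, while all day 10 H3K27ac regions did so in 75.9% and 73.5%. Regions that lost H3K27ac at day 10 lay on H3K4me1 in 73.8% of cases at day 0 and 42.5% at day 10, while all day 0 H3K27ac regions did so in 83.2% and 66.3%. At day 32 the gained regions lay on H3K4me1 of day 0 in 61.7% and of day 32 in 82.9%, and the lost ones in 67.7% and 55.4%; all day 32 H3K27ac regions did so in 80.5% and 83.4%, and all day 0 ones in 83.2% and 81.4%. Judged by single H3K4me1 libraries, the regions gained at day 10 had a peak in 55.9 ± 0.0328% at day 0 and 79.7 ± 0.268% at day 10 (SD, n = 2). No test was run over regions, which are not independent replicates.

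Of the regions that gained H3K27ac at day 10, 2372 had no H3K4me1 peak at day 0 and one in both H3K4me1 libraries of day 10. At day 32, 16.6% of these 2372 had both marks in both libraries, 25.0% had H3K4me1 without H3K27ac, 1.64% had H3K27ac without H3K4me1, 19.3% had neither, and 37.4% differed between replicates. At day 22 the shares with H3K4me1 alone and H3K27ac alone were 14.4% and 3.58%; at day 18 they were 1.52% and 2.32%, with 68.1% differing between replicates. Among the 1419 with no H3K27ac peak at day 32, 41.9% had an H3K4me1 peak in both libraries (exact binomial 95% interval 39.3% to 44.5%), 57.6% in replicate 1 and 51.9% in replicate 2. The same share was 41.1% of 830 at day 22 and 16.7% of 215 at day 18, where it was 86.5% in replicate 1 and 16.7% in replicate 2. H3K4me1 lists covered more bases than H3K27ac lists at day 32, 137 ± 8.21 Mb against 73.5 ± 3.13 Mb (SD, n = 2). At day 18 the H3K4me1 list of replicate 2 was short, with 111741 peaks. These shares were not computed with lists of equal length, so how far they follow list length is unknown. On chromosome 6 at 64484673 to 64506050, where neither mark had a peak at day 0, H3K27ac covered 7.83 ± 1.21 kb at day 10 and 1.82 ± 0.174 kb at day 32, while H3K4me1 covered 6.03 ± 0.102 kb and 5.34 ± 0.599 kb (SD, n = 2).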

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

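No test was run in this part. Its results were singled out because both libraries of one RAS day lay above both day 0 libraries and both of another lay below them; the difference was not tested. H3K4me1 peaks covered 97.3 Mb on average at day 10 and 108 Mb at day 22, with both libraries of each day below both day 0 libraries, and 137 Mb at day 32, with both above. The margin at day 32 was narrow, with 131.55 Mb in replicate 2 against 131.03 Mb in day 0 replicate 2. The median width of an H3K4me1 peak averaged 406 bases at day 10, 430.5 at day 22 and 511.5 at day 32, against 485 and 491 in the day 0 libraries. The number of H3K4me1 peaks did not part day 10 from day 0 in this way, with 184858 and 172361 peaks at day 10 and 177806 and 179798 at day 0.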

How the results depend on the processing

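The settings without day 18, and all those for similarity to day 0, were chosen after seeing the data. The same-day similarity kept its side of the threshold under each alternative run, and the relation to distance in days stayed outside it. Depth is unknown, so equal list lengths are the nearest check of it. The planned gene list and motif alternatives were not run.

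With lists of equal length, H3K27ac at day 18 had 10404 gained and 8653 lost regions, and H3K4me1 gains were 10648 at day 10, 8463 at day 22, 7626 at day 32 and 13328 from day 10 to 32. H3K27ac bins lost in all 8 RAS libraries were 11376 (exact permutation p = 0.0444, now under 0.05 before adjustment and 0.0593 after it). The share of regions lost at day 10 with a peak in both day 32 libraries was 43.8% for H3K27ac and 40.9% for H3K4me1. H3K27ac gains lay on day 0 H3K4me1 in 35.6% at day 10, 39.0% at day 18, 41.6% at day 22 and 46.4% at day 32, where H3K4me1 lists were shortened.

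With a −log10 q of 5 or more, H3K4me1 gains were 8337, 3476 and 8002 at days 10, 18 and 22, and losses from day 10 to 32 were 3289. The share with a peak in both day 32 libraries was 52.4% for H3K27ac losses and 41.7% for H3K4me1 gains of day 10. H3K27ac gains lay on day 0 H3K4me1 in 45.5%, 44.9%, 51.9% and 55.0% at days 10, 18, 22 and 32. The cause was not tested.

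Asking for 50% coverage calls more regions by construction. H3K27ac losses were 25160, 8923, 19081 and 9417 at days 10, 18, 22 and 32, gains 18925 at day 22 and 15769 at day 32, and 24564 were gained and 10689 lost from day 10 to 32. H3K4me1 gains were 27541, 15014, 23808 and 26156 and losses 51588, 29953, 39037 and 18525 at those days, with 46504 gained and 13547 lost from day 10 to 32. The shares with a peak in both day 32 libraries were 45.9% for H3K27ac losses and 33.4% for H3K4me1 gains, and H3K27ac gains lay on day 0 H3K4me1 in 50.8% at day 10 and 57.2% at day 22. With merged regions, 1663 gained H3K4me1 in all 8 RAS libraries (exact permutation p = 0.0444, adjusted 0.0593). Without day 18, H3K27ac bins lost numbered 18910 (p = 0.0357, exact permutation). Without the day 32 libraries, rho of similarity to day 0 with day was 0.72 for H3K27ac and 0.60 for H3K4me1 (exact permutation p = 0.178 and 0.267), over fewer samples. With whole days permuted, rho was 0.878 and 0.830 (exact permutation p = 0.167 and 0.0833), where the smallest p that 24 orders can give is 0.0417.

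Leaving out 1 replicate moved 75 values and left 29 within their limits, since 1 library fewer has to hold or lack the peak. It tends to raise the side of the day that the replicate belongs to, so a turn of the larger side is no measure of dependence on 1 library. H3K27ac gains ranged from 13759 to 25587 at day 10, 20707 to 54460 at day 18, 13432 to 24509 at day 22, 10335 to 23280 at day 32 and 17422 to 30416 from day 10 to 32. H3K27ac losses ranged from 17261 to 39180, 8719 to 18172, 13939 to 32100, 7640 to 21527 and 8529 to 16153. H3K4me1 gains ranged from 21079 to 39320, 8412 to 63226, 18081 to 35404, 19373 to 33635 and 31135 to 50353, and losses from 34397 to 55929, 17611 to 60686, 26556 to 44769, 13709 to 26148 and 10346 to 24117. The shares with a peak in both day 32 libraries ranged from 23.8% to 47.1% for H3K27ac gains, 30.7% to 60.3% for its losses, 26.2% to 53.3% for H3K4me1 gains and 35.3% to 62.7% for its losses.

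Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated from -0.0685 to 0.0395 for H3K27ac and from -0.00187 to 0.0218 for H3K4me1. With the replicate block, the same-day indices were 0.639 and 0.551 (exact permutation p = 0.00833 and 0.0167). The counts of gained and lost regions come from no test, so the block was not applied to them.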

Other observations

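The tests of depth and of weak calls for day 18 replicate 1 were chosen after the result was seen; the other tests below were fixed before their results, on patterns already noticed in these data.

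Chromosomes differed in how much H3K27ac they lost at day 10. Chromosome 19, with 35.0 day 0 regions per Mb, lost 38.8% of them, and chromosome 4, with 14.6 per Mb, lost 20.4%. Gains ran the other way, with 7.63% of the day 10 regions of chromosome 19 and 28.1% of those of chromosome 4. Over 22 autosomes, which are not independent replicates, the percent lost against the density of day 0 H3K27ac regions had Pearson's r of 0.644 (permutation p = 0.00273, adjusted over 16 relations 0.00546) and Spearman's rho of 0.610 (permutation p = 0.00344, adjusted 0.0138). In the H3K27ac relations here, density and percent both come from the same day 0 lists. A chromosome with more peaks called at day 0 would tend to show more losses and fewer gains. Permuting chromosomes does not remove this, and how far it sets the relations was not tested. Without chromosomes 17 and 19 r was 0.341 and rho 0.510, so much of r rests on those chromosomes. H3K27ac losses at day 18 had the opposite sign, with r of -0.509 (permutation p = 0.0154, adjusted 0.0189) and rho of -0.372 (permutation p = 0.0896, adjusted 0.130). At days 22 and 32 r was 0.665 and 0.595 (permutation, adjusted 0.00546 and 0.0113) and rho 0.447 and 0.471 (adjusted 0.0688 and 0.0646). H3K4me1 losses at day 10, set against the same H3K27ac density, had r of 0.602 (permutation p = 0.00925, adjusted 0.0123) and rho of 0.00508 (permutation p = 0.984, adjusted 0.984). Without chromosomes 17 and 19 these 4 values of r were -0.228, 0.257, 0.239 and -0.0757. For H3K27ac gains at day 10 r was -0.733 and rho -0.650 (permutation p = 0.000210 and 0.00150, adjusted 0.00168 and 0.00971), and without chromosomes 17 and 19 r was -0.502 and rho -0.549; H3K4me1 gains at day 10 had r of -0.653 and rho of -0.460 (permutation, adjusted 0.00546 and 0.0661), and -0.195 and -0.296 without those chromosomes.

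Weaker day 0 peaks on dense chromosomes are argued against for losses at day 10. Matched on peak strength, chromosome 19 would have lost 20.1% and chromosome 4 27.3%, and rho after matching was 0.627, and 0.579 to 0.619 with each of the 4 libraries left out. Whether 1 deviant library sets the relation stays open, since unmatched rho was 0.486 without day 0 replicate 1, between the bounds set for the test. Matching on strength does not remove the shared use of the day 0 lists. Base composition and gene density, which may go with region density, were not tested for lack of a genome of this build, and no biological explanation was tested.

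H3K27ac gained at day 10 was kept more often where H3K4me1 had been present before. Of 6106 gained regions with an H3K4me1 peak in both day 0 libraries, 41.1% had H3K27ac in both day 32 libraries, against 19.9% of 4574 regions with none. Per day 32 library the shares were 54.4 ± 5.93% and 28.9 ± 4.13% (SD, n = 2). The difference of 21.3 percentage points was 19.04 after matching on day 10 peak strength and 18.4 after matching on region width, so neither explains most of it. H3K27ac below the calling threshold at day 0 at these sites remains open, and no biological explanation was tested.

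The H3K27ac list of day 18 replicate 1 stood apart, with Jaccard indices of 0.319 to 0.439 to lists of other days against 0.438 to 0.590 for replicate 2. Weak calls near the threshold stay open in part. Of the peaks in no other list, 49.5% passed a −log10 q of 5, above the highest of the other 9 lists, 39.6%. That share was below the 83.3% of all peaks of this list, and the bound was chosen after the result was seen. A library of the other mark is argued against by a mean index of 0.397 to the other H3K27ac lists and at most 0.302 to an H3K4me1 list. Greater depth cannot be told apart by the fold spacing, 0.289 against a median of 0.245 in the other lists (SD 0.0450), since it lies above the median by less than the SD and the measure was not calibrated. A day 18 state shared by both replicates also stays open: replicate 2 held 25.8% of the peaks that no other day had, and the bound of 50% set for this test was wrong, because libraries of other days ranged from 16.7% to 66.8%, and was replaced by that range after the result was seen. In the other direction, replicate 1 held 51.5% of the peaks of replicate 2 that no other day had, above 50% but within the range of the other days. Both day 18 lists had more peaks that no other day held, 24.4% and 14.0%, than the other 8 lists, 2.54% to 10.5%. They were also the longest H3K27ac lists, with 131866 and 119660 peaks used against at most 99469 in the others. These shares were not computed with lists of equal length, so how far they follow list length is unknown.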
